A study of Mus musculus with 5 samples.

How the data were processed

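Triptolide, a diterpenoid from the vine Tripterygium wilfordii, had been given to male C57BL/6J mice aged 10 weeks by gavage at 50 µg per kg of body weight per day. Control mice received saline. Testes were taken after 35 days, and the labels give 6 mice per group. The data examined here are 5 RNA-seq libraries, 2 control and 3 triptolide. Per the labels' protocols, ribosomal RNA was removed from total RNA, and strand-specific libraries were sequenced as read pairs. The labels do not say whether each library is 1 animal or a pool, so p-values measure only the spread between these libraries.

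Per the submitters' processing notes, the tools were HISAT2 2.0.1, HTSeq 0.6.1, DESeq with no version, and bedtools 2.17.0, with no role stated for each. Those notes name the build hg19, which is human. The coordinates are nevertheless mouse: of the 9796 circRNAs whose host gene symbol is in the RefSeq gene table for GRCm38.p6, 9708 (99.1%) lay inside that gene. Coordinates are therefore printed as the deposited files give them, and the RefSeq table served only for names and for which genes neighbour each other.

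The authors deposited 3 tables. The mRNA table holds expected counts and FPKM for 103639 Ensembl transcripts, per the file headers. Its deposited FPKM were found to equal the expected count divided by a length that is the genomic span of the transcript, introns included, and that reaches 4434882 bases, less an average fragment length. That fragment length was estimated per library from a weighted line through transcripts of 800 to 20000 bases with an FPKM above 20. The table pairs no transcript with a gene name, and none of the 103639 IDs is in the name tables used here. No gene of the mRNA table is therefore named, and 4 transcripts are given by ID. The gene lists, the comparison of circRNAs with their host mRNA and that of lncRNAs with neighbouring mRNAs, all planned on this table, could not be run.

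The lncRNA table holds expected counts, per the file headers, for 33057 assembled transcripts at 16356 loci, with coordinates, class (intergenic, antisense or intronic) and whether the authors listed the transcript as known. Of 7976 Ensembl gene IDs in it, 7892 had a symbol. An antisense or intronic locus carries the symbol of the gene it overlaps. The strand setting used in counting is not given in the sources used here, so reads of an antisense locus and of its partner gene cannot be told apart for certain. The circRNA table holds a score deposited by the authors for 11957 circRNAs. From its name it is SRPBM, back-splice junction reads scaled to the mapped reads of the library, here rounded to whole numbers. Its low values are whole multiples of 8.23 to 9.5 SRPBM, the worth of 1 read. The smallest value listed was 2 reads. What a 0 stands for is not given in the sources used here, and some circRNAs with many reads in every other library were at 0 in 1 library, so a 0 is described only as listed at 0. Dividing by that step gave values within 0.1 of a whole read for 93.6% to 94.9% of the entries above 0.

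Columns were matched to samples by their headers. Among the lncRNA columns, 2 share the header of triptolide replicate 2, and 3 of the circRNA columns share that of triptolide replicate 1. They were used as triptolide libraries without a number and are called A and B, or A, B and C. These letters do not match between the tables. The 5 FPKM columns beside the lncRNA counts were not used.

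Expected counts were rounded and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling and the quasi-likelihood F test, triptolide against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, edgeR had been fixed for tables with raw counts and limma on log2(FPKM + 1) for tables without. The table holds expected counts, so edgeR was used on them and limma is given beside it. Standard errors of log2 fold changes were taken from the F statistic. CPM is the count scaled to the total count of the same library and table. For lncRNAs, expected counts were also summed per locus and tested in the same way, which was decided after the values were seen. circRNAs above 0 in at least 2 libraries were tested with limma 3.58.1 (trend) on log2(SRPBM + 16), where 16 is the smallest value above 0. Fold changes on that scale understate the change of low circRNAs. Totals per library were compared by two-sided exact permutation over the 10 assignments of 5 libraries, whose smallest possible p is 0.1. In all, 35 gene lists (testis cell types, other cell types the tissue could hold, pathways and named lncRNAs) were fixed beforehand. They were tested with camera (correlation 0.01) and fry on lncRNA loci by symbol and on circRNA host genes, for lists with at least 5 tested members.

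The rule for named items was fixed at the same time. Without overlap between the libraries of the groups, it took the largest rises and falls past the threshold, 8 per direction for mRNA (mean FPKM of at least 1 in the higher group) and 5 per direction for lncRNA (at least 0.5) and circRNA. It filled up with the smallest unadjusted p where fewer passed. It added the 3 members of the fixed list of named lncRNAs with the smallest p and the 3 most abundant circRNAs. Called loci with a symbol and the smallest p, 8 per direction, were added after the values were seen, as were called members of the lists, the 3 mRNA transcripts picked from the 20 most abundant, and the locus given as an example in the closing section. Where both controls were at 0, the fold given is that of the triptolide mean over a control floor of 3 counts over the group. That floor is 1.47 CPM in the lncRNA table and 0.0902 CPM in the mRNA table. The spread of the triptolide libraries is left out of these folds. Such floors and intervals cover counting error only.

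The tests were run on simulated data with 200 changed features, drawn among those with a mean of at least 50 counts, or 20 reads for circRNAs. Counts were drawn with the dispersion estimated for each feature. For lncRNA loci (6551 tested), 76 of 100 features with a 2-fold change and all 100 with a 4-fold change were recovered, with 3 unchanged loci called. For mRNA transcripts (32805 tested), edgeR recovered 0 of 100 and 0 of 97. DESeq2 1.42.0 recovered 18 of 100 and 49 of 97 but called 369 unchanged transcripts. Drawn with the smaller common dispersion of lncRNA loci, 1 value for all transcripts (34013 tested), 60 and 100 of 100 mRNA transcripts were recovered. The spread of transcript counts thus limits the test. Whether by its size or by its unevenness between transcripts is not settled, as both differed between these runs. With only 200 changed features the adjusted threshold is also stricter than where many features change. For lncRNA transcripts (11895 tested) 0 of 100 were recovered at either fold. For circRNAs (3815 tested) 0 of 100 at 2-fold and 6 of 100 at 4-fold were recovered.

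Total expected counts ranged from 15442421 to 19539236 per library for mRNA and from 947298 to 1071012 for lncRNA. Within groups, counts of every pair of libraries differed by more than counting noise (chi-square per degree of freedom of 4.89 or more over lncRNA loci), so no library counted as a copy of another. Alternatives covered pseudocounts, filters, scalings, a 2-fold limit, limma and DESeq2, library weights, the replicate number as a block, and each library left out.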

Results

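RNA was profiled in mouse testis after 35 days of triptolide (50 µg per kg per day, 3 libraries) or saline (2 libraries), to ask which long non-coding RNAs and circular RNAs differ after exposure. Total expected counts of mRNA transcripts were 15442421 and 17799497 in control and 17812872, 18006490 and 19539236 in triptolide libraries. Those of lncRNAs were 964886 and 1071012 in control and 947298, 1058427 and 1029547 in triptolide libraries. For circRNAs the deposited values correspond to 40071 and 43745 junction reads in control and 32846, 44370 and 35374 in triptolide libraries. The groups also differed in a property of the sequenced material. The average fragment length implied by the mRNA table was 283 ± 8.1 bases (SD, n = 2) in control and 260 ± 3.7 bases (SD, n = 3) in triptolide, with no overlap (two-sided exact permutation p = 0.1, the smallest that 2 against 3 libraries allow).

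Summed over each lncRNA locus, an analysis chosen after the values were seen, counts differed at many loci after triptolide, and Malat1 was the most abundant of the named loci that rose. Malat1, a nuclear lncRNA (chromosome 19, 5795691 to 5802671), rose 3.44-fold, from 2764 ± 369 CPM (SD, n = 2) to 9493 ± 1918 CPM (SD, n = 3). Its log2 fold change was 1.78 ± 0.18 (SE), with adjusted p = 1.8e-07 in edgeR's quasi-likelihood test. Lncpint, a p53-induced lncRNA (chromosome 6, 31159841 to 31218346), rose 4.28-fold, from 153 ± 11.3 to 651 ± 114 CPM. An antisense locus at 4930533L02Rik (chromosome 7, 125306594 to 125320287) rose 6.82-fold, from 48.0 ± 3.4 to 328 ± 80.6 CPM. Among falls, Cep83os (chromosome 10, 94673493 to 94688613), next to the centrosomal gene Cep83, dropped 2.20-fold, from 2438 ± 55.8 to 1108 ± 59.3 CPM. A locus antisense to Topaz1, a germ-cell gene required for male meiosis (chromosome 9, 122779737 to 122799515), fell 3.35-fold, from 394 ± 74.6 to 118 ± 3.3 CPM. Whether counting used the strand is not given in the sources used here, so values at antisense loci, here and below, may include reads of the partner gene.

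Of 6888 lncRNA loci tested, 501 passed an adjusted p of 0.05, 345 higher and 156 lower in triptolide. The median log2 fold change was 1.28 for loci that rose and -1.02 for those that fell. By class, 208 intergenic loci rose and 104 fell of 4086 tested, 94 antisense loci rose and 33 fell of 1937, and 12 intronic loci rose and 5 fell of 214. Of 1760 loci with a transcript listed as known, 87 rose and 51 fell, against 258 and 105 of the 5128 others. The share of rises among calls did not differ detectably between these kinds (two-sided Fisher's exact p = 0.085). The planned test, on single lncRNA transcripts, called 0 of 13534 with edgeR, with 1339 at an unadjusted p under 0.05, while DESeq2 called 327 and limma 2. Without control 1, triptolide A or triptolide 3, the locus calls numbered 269, 279 and 269.

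The largest rises by the fixed rule were at loci with few or no counts in control. XLOC_060941 (chromosome 14, 9159277 to 9161235) had 0 counts in both controls and 26, 29 and 20 in triptolide, a mean 16.8-fold above the control floor (adjusted p = 5.2e-05, edgeR). XLOC_175191 (chromosome 7, 125289506 to 125291157) had 0 counts in both controls and 12, 5 and 30 in triptolide, a mean 10.5-fold above the control floor. That mean leaned on triptolide 3, at 29.1 CPM against 12.7 in triptolide A and 4.72 in triptolide B. A locus antisense to Tmem191c (chromosome 16, 17276551 to 17278026) had 0 and 0 against 6, 14 and 11 counts, a mean 6.84-fold above the control floor. XLOC_151016 (chromosome 5, 116091162 to 116092871) averaged 1.56 ± 2.2 CPM in control (3 and 0 counts) and 28.9 ± 13.8 CPM in triptolide. XLOC_055861 (chromosome 14, 24665217 to 24772836) averaged 0.518 ± 0.73 (1 and 0 counts) and 11 ± 4.4 CPM. Without control 1, the remaining control was at 0 for both. The largest falls were at XLOC_090217 (chromosome 17, 74714652 to 74717645), 89 bases from the tetratricopeptide gene Ttc27, and at a locus antisense to A1cf (chromosome 19, 31925580 to 31932635). The former dropped 11-fold, from 23 and 16 counts in control to 0, 0 and 5 in triptolide, and the latter 9.17-fold, to 1.94 ± 0.89 CPM. The drop at XLOC_090217 was 7.21-fold without triptolide B, and without triptolide 3 both remaining triptolide libraries were at 0. XLOC_094560 (chromosome 18), XLOC_030506 (chromosome 11) and XLOC_072177 (chromosome 15) dropped 7.10-fold, 6.75-fold and 5.28-fold, and without control 1 the drops of XLOC_094560 and XLOC_072177 were 4.63-fold and 3.43-fold. These loci had at most 46 counts in any library. Several did not pass with 1 library left out. Without control 1 the adjusted p in edgeR was 0.11 for Tmem191c, 0.072 for XLOC_055861, 0.19 for XLOC_090217, 0.36 for XLOC_094560, 0.082 for XLOC_030506 and 0.43 for XLOC_072177. Without control 2 it was 0.085 for Tmem191c, 0.18 for XLOC_055861 and 0.18 for A1cf, and without triptolide 3 it was 0.070 for XLOC_072177. With limma in place of edgeR the adjusted p was 0.096 for Tmem191c, 0.085 for XLOC_055861, 0.096 for XLOC_090217 and 0.059 for A1cf.

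Other named loci moved in both directions, chosen by their p after the values were seen. AI480526 (chromosome 5, 2.79-fold) and Gm42654 (chromosome 5, 2.80-fold) rose. So did antisense loci at Gm11631 (chromosome 11, 3.48-fold) and 9530077C05Rik (chromosome 9, 4.70-fold). A locus antisense to Ccer1, a spermatid gene, rose 4.28-fold, from 27.9 ± 2.8 to 120 ± 32.9 CPM. Gm11335, in the histone region of chromosome 13 (23526812 to 23530943) and 100 bases from the histone gene H4c8, fell 5.12-fold, from 168 ± 1.9 to 32.6 ± 4.3 CPM. 4930463O16Rik (chromosome 10) fell 2.15-fold, the Gm43640/Gm33847 locus (chromosome 5) 2.18-fold and 2610035D17Rik (chromosome 11) 2.46-fold. Antisense loci at Adk, which encodes adenosine kinase, and at Fntb, a farnesyltransferase subunit, fell 3.45-fold and 2.79-fold.

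**Figure D1:**
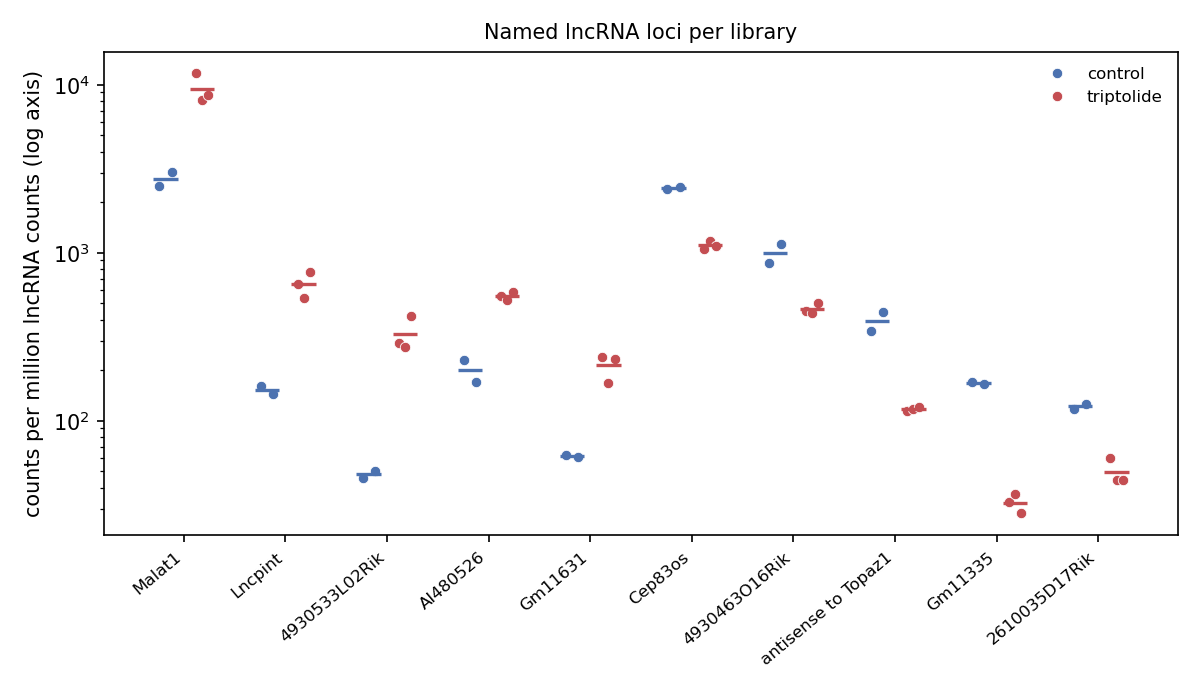
CPM (log axis) of 10 named lncRNA loci, with 1 point per library, 2 control and 3 triptolide, and a bar at the group mean. Malat1 lies between 8059 and 11670 CPM in triptolide against 2503 and 3024 in control, and Cep83os averages 1108 against 2438. The points labelled 4930533L02Rik and Gm11631 are of antisense loci at those genes.

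Few lncRNA loci carried the name of a gene from the 35 fixed lists: 63 were tested, of which 5 rose and 1 fell. Of 8 tested loci from the fixed list of named lncRNAs only Malat1 passed, and 2 passed adjusted over the list alone. In lists this small that adjustment, here and below, is lenient, and it is not corrected across lists. Of all tested loci, 21.7% had an unadjusted p under 0.05 in edgeR, so such passes do not set a list apart. The Gm26953/Miat locus, of antisense class with known and new transcripts, averaged 78.1 ± 25.5 CPM in control and 127 ± 6.6 CPM in triptolide (adjusted p = 0.080, edgeR). Its log2 fold change of 0.69 lay between 0.38 and 1.12 with 1 library left out. The Nespas/Gnas locus, of antisense and intronic class, averaged 849 ± 2.5 and 1139 ± 318 CPM (adjusted p = 0.21, edgeR, and 0.015 without triptolide B). Its log2 fold change of 0.43 lay between 0.24 and 0.67 with 1 library left out. Of 6 loci at genes of elongating spermatids, 2 rose, and 2 passed adjusted over the list alone. They were an antisense locus at Smcp, which encodes a sperm mitochondrial capsule protein, from 10.9 ± 3.6 to 36.9 ± 15.3 CPM, and an intronic locus at Gapdhs, the sperm glycolytic enzyme, from 21.6 ± 0.20 to 52.6 ± 19.4 CPM. A larger antisense locus at Gapdhs overlaps the latter, so reads of the pair cannot be assigned for certain. The Gapdhs locus was also the 1 of 5 glycolysis loci that rose, and the 1 that passed adjusted over the list alone. Of 5 axoneme loci 0 passed in edgeR, and 1, antisense to Tekt1 (59.7 ± 6.5 and 33.1 ± 6.7 CPM), passed adjusted over the list alone. Of 4 loci at genes of spermatid chromatin remodelling and 3 at antioxidant genes 0 passed in edgeR. In each list 1 passed adjusted over the list alone, at the bromodomain gene Brdt (51.6 ± 13.5 and 85.2 ± 13.7 CPM) and antisense to Srxn1, the sulfiredoxin gene (41.0 ± 5.1 and 72.3 ± 14.2 CPM). Another locus antisense to Brdt went the other way, at 48.1 ± 2.0 and 39.3 ± 5.8 CPM (adjusted p = 0.64, edgeR).

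None of the 4 lists with at least 5 tested loci stood apart as a set, namely elongating spermatids, axoneme, glycolysis and named lncRNAs (camera adjusted p of 0.43 to 0.91, and adjusted p of 0.83 or more with an estimated correlation). For axoneme and glycolysis loci the median and camera's direction differed in sign. In fry's mixed test, for change in either direction, the adjusted p was 0.022 for elongating spermatids, 0.022 for the axoneme, 0.0072 for named lncRNAs and 0.063 for glycolysis. That test does not compare a list with the other loci. As 21.7% of all tested loci had an unadjusted p under 0.05 in edgeR, it does not set these lists apart. Single loci that passed were antisense to Bcl2l1, the gene of the survival protein Bcl-xL (5.39 ± 0.30 to 32.0 ± 9.8 CPM, higher), at the drug efflux gene Abcg2 (125 ± 13.2 to 243 ± 38.2 CPM, higher) and antisense to Asns, an amino acid stress gene (62.1 ± 6.0 to 31.7 ± 7.4 CPM, lower). The antisense locus at Star, the cholesterol carrier of Leydig cells, averaged 55.4 ± 3.6 and 37.8 ± 4.6 CPM (adjusted p = 0.28, edgeR). Over all loci and adjusted over the list alone, 0 loci passed in edgeR for meiotic prophase (4 tested), round spermatids (1), Leydig cells (3), smooth muscle (1), epididymis (1), fat cells (1), blood-testis barrier (2), the piRNA pathway (2) and p53 targets (4). The same held for inflammation (1), heat shock (3), fatty acid metabolism (3), cholesterol synthesis (1), ribosomal proteins (2) and regulators of circRNA formation (3). The lists for spermatogonia, Sertoli cells, immune cells, endothelium, fibroblasts, red blood cells, TFIIH and RNA polymerase II, sperm ion channels, mitochondrial mRNAs, immediate early genes and histones had 0 tested loci. With 1 library left out, the adjusted p in edgeR for Smcp was 0.058 without control 2 and 0.11 without triptolide 3, and that for Abcg2 was 0.060 without triptolide A. That for Gapdhs was 0.072 without control 1, 0.051 without control 2, 0.13 without triptolide A and 0.13 without triptolide 3. That for Asns was 0.20 without control 1, 0.085 without control 2, 0.087 without triptolide A, 0.063 without triptolide B and 0.15 without triptolide 3. DESeq2 gave adjusted p of 0.065 for Gapdhs and 0.11 for Asns, which edgeR did not pass with no filter (0.061) or a mean count of at least 10 (0.053) either. All of these differences coincide with the shorter fragments of the triptolide libraries.

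In the mRNA table, 6 of 35123 transcripts passed the test and all 6 were higher in triptolide. ENSMUST00000075141 had no counts in either control and 92.3 ± 7.6 CPM in triptolide, a mean 1020-fold above the control floor (adjusted p = 0.044, edgeR's quasi-likelihood test). ENSMUST00000028608 also had none in control and reached 50.1 ± 3.8 CPM, a mean 555-fold above the control floor. Whether the genes of these transcripts changed is open, since the table pairs no transcript with a gene. Of transcripts with lower values, 0 passed in edgeR. The smallest p among them were those of ENSMUST00000099703, at 118 ± 16.6 CPM in control and 10.4 ± 0.91 CPM in triptolide, and of ENSMUST00000172108, at 85.8 ± 42.6 and 0.159 ± 0.012 CPM (adjusted p = 0.055 for both, edgeR). Both passed with DESeq2, and the former also with limma on log2(FPKM + 1). Among the 20 most abundant transcripts, looked at after the values were seen, 2 with spans of 561 and 726 bases averaged 4367 ± 1528 and 3785 ± 536 CPM in control and 674 ± 155 and 936 ± 179 CPM in triptolide. Another, with a span of 6983 bases, averaged 1353 ± 114 CPM in control and 3400 ± 416 CPM in triptolide. These 3 had adjusted p of 0.059, 0.058 and 0.073 in edgeR, and passed with DESeq2 and with limma on log2(FPKM + 1). Without gene names, whether any of them is a non-coding RNA that was also counted among the lncRNAs could not be checked.

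At an unadjusted p under 0.05, 7995 mRNA transcripts differed (22.8%), 4461 higher and 3534 lower. The number called depended on the model. DESeq2 called 8134 (4853 higher, 3281 lower), and limma on log2(FPKM + 1), the test fixed for a table without counts, called 169 (107 higher, 62 lower). With any 1 library left out edgeR called 0, and without TMM scaling it called 6 higher and 1 lower. In simulations edgeR recovered 0 of 97 transcripts with a 4-fold change, so a low count does not show that few transcripts changed. Changes tilted with the length of genome a transcript spans. The median log2 fold change was -0.26 in the 10% of transcripts with the shortest spans (123 to 1702 bases) and 0.19 in the 10% with the longest (116673 bases or more). Leaving out TMM scaling moved the median of all transcripts by 0.118 (log2), and these medians to -0.15 and 0.30. The difference of 0.45 was 0.30 without triptolide 3. Set against the mean of all 5 libraries, longest minus shortest was -0.21 and -0.30 in control 1 and 2, 0.23 and 0.51 in triptolide 1 and 3, and -0.13 in triptolide 2, which lay with the controls. Fragment lengths were 289 and 278 bases in control 1 and 2 and 257, 264 and 258 bases in triptolide 1, 2 and 3. More transcripts were detected in triptolide than in control, 43799 ± 443 (SD, n = 3) against 40909 ± 685 (SD, n = 2), with a two-sided exact permutation p of 0.1, the smallest possible. In rounded counts thinned to the smallest library total, 42536, 41870 and 42531 were detected in triptolide 1, 2 and 3, against 39377 and 39938 in control 1 and 2.

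**Figure D2:**
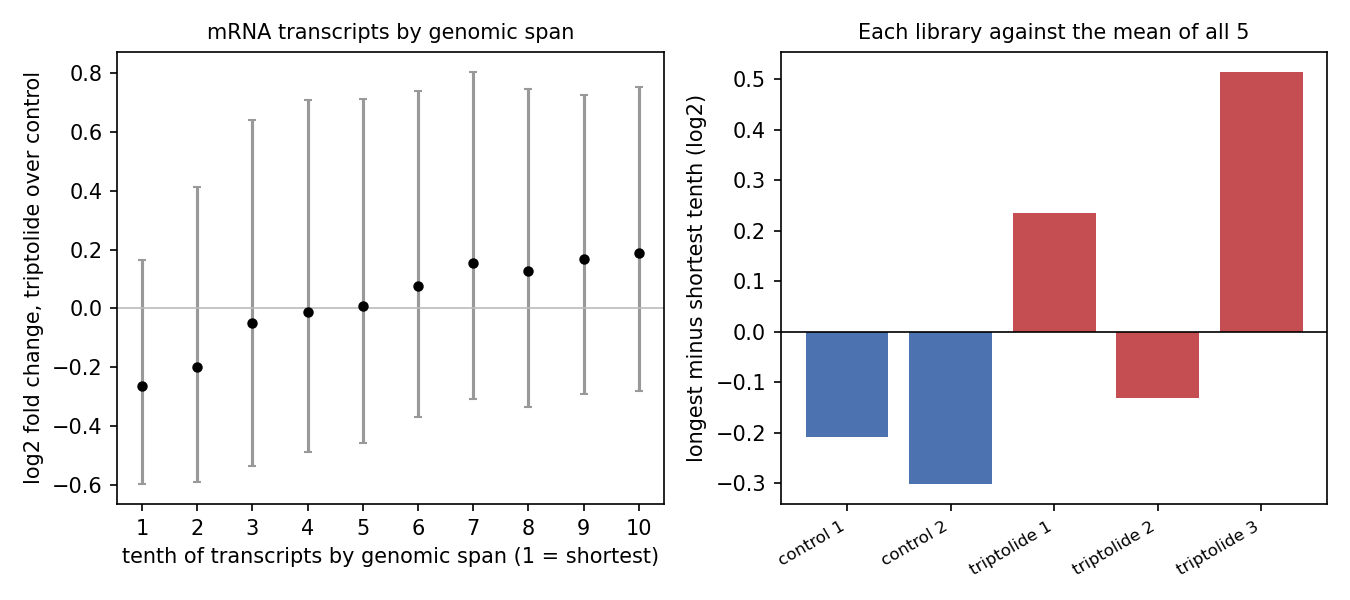
Left, median log2 fold change (triptolide over control) of mRNA transcripts in 10 bins by genomic span, with bars from the lower to the upper quartile, running from -0.26 to 0.19. Right, the longest minus the shortest bin (log2) in each library against the mean of all 5, from -0.30 in control 2 to 0.51 in triptolide 3.

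Among circRNAs, 0 passed, and the smallest p among those lower in triptolide was that of a circRNA from Prm2, which encodes protamine 2, a protein that packs DNA in sperm. This circRNA (chromosome 16, 10791405 to 10791857) had 624 and 290 SRPBM in control and 86, 79 and 52 in triptolide, a log2 fold change of -2.35 ± 0.44 (SE) on the log2(SRPBM + 16) scale. Its adjusted p was 0.68 among all 5457 circRNAs tested with limma, and 3.4e-05 among the 1404 above 0 in all 5 libraries, where it alone passed. Lower values without passing were also found for circRNAs of Fam151b (chromosome 13, 92466977 to 92477953), at 197 ± 44.6 SRPBM in control (SD, n = 2) and 57.3 ± 16.7 in triptolide (SD, n = 3), and of Fam193a (chromosome 5), Wwc2 (chromosome 8) and Hipk3 (chromosome 2), all listed at 0 in every triptolide library. Higher values without passing were found for a circRNA of Rgs22, a regulator of G-protein signalling (chromosome 15, 36010288 to 36025987), listed at 0 in both controls and at 124, 124 and 104 SRPBM in triptolide. One of the cytoskeletal linker Macf1 (chromosome 4, 123536202 to 123554365) had 0 and 16 against 105, 132 and 165 SRPBM. Those of Uhrf1bp1l (chromosome 10), Ahcyl2 (chromosome 6) and Ube3a (chromosome 7) were listed at 0 in both controls and averaged 88.7 ± 38.9, 77.3 ± 32.7 and 71.3 ± 20.7 SRPBM in triptolide. Without control 2 the adjusted p in limma was 1.8e-06 for Prm2, 0.00060 for Rgs22, 8.3e-05 for Macf1 and 0.034 for Uhrf1bp1l, and without control 1 it was 0.038 for Rgs22. For Prm2 the log2 fold change was -1.81 without control 1 (adjusted p = 0.78, limma) and -2.88 without control 2. Those of Prm2, Rgs22 and Macf1 also passed among all circRNAs above 0 in at least 1 library. Over all alternatives the adjusted p reached 0.95 or more for each of these 4.

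The most abundant circRNA came from Bbs9, a gene of the ciliary BBSome (chromosome 9, 22643745 to 22679064). It averaged 12030 ± 3719 SRPBM in control and 7798 ± 757 in triptolide (adjusted p = 0.68, limma), with 14660 and 9396 SRPBM in control 1 and 2. Its log2 difference of -0.59 was -0.27 without control 1, -0.91 without control 2 and 0 under quantile normalization. Its adjusted p was 0.0031 among all circRNAs above 0 in at least 1 library and reached 1 under other alternatives. The other abundant Bbs9 circRNA (22643745 to 22659145) averaged 4302 ± 1504 and 2617 ± 281 SRPBM, with a log2 difference of -0.67 that was -0.31 without control 1 and -1.04 without control 2. The circRNA of the chromatin remodeller Ep400 (chromosome 5, 110753804 to 110756766) averaged 5488 ± 636 and 5232 ± 443 SRPBM. In limma 360 circRNAs had an unadjusted p under 0.05 (98 higher, 262 lower), and edgeR on recovered junction reads called 0 of 931, with 33 at an unadjusted p under 0.05. DESeq2 on the same reads also called 0, with 17, and edgeR with no filter called 5. Control 1 stood apart in circRNA reads. Over 271 circRNAs with a mean of at least 20 reads, it differed from the other libraries by a chi-square per degree of freedom of 13.7 to 14.6, against 3.33 to 3.53 between control 2 and triptolide libraries and 2.09 to 2.83 among triptolide libraries. Abundant circRNAs were listed at 0 in control 1 alone. With at least 10 reads in each of the other libraries, 76 circRNAs were at 0 in control 1, against 1 in control 2 and 2, 2 and 1 in triptolide A, B and C. Among them were circRNAs of Spag16, an axoneme gene (chromosome 1, 69858473 to 69896581, 0 and 720 SRPBM in control and 707, 593 and 409 in triptolide), and of Crem, a spermatid transcription factor (chromosome 18, 3287904 to 3327591, 0 and 381 against 210, 354 and 209), both picked after their values were seen. Leaving such circRNAs aside, the chi-square for control 1 was 4.49 to 4.92, against 2.67 to 3.03 for control 2 and triptolide, and limma and edgeR again called 0, with 353 and 52 at an unadjusted p under 0.05. Among circRNAs above 0 in at least 1 library limma called 36 (34 higher, 2 lower), and 33 of the rises were listed at 0 in control 1. It called 130 without control 2 (122 higher, 8 lower), where 120 of the rises were at 0 in control 1 and 76 of them in control 1 alone, and 2 without control 1, both higher, those of Rgs22 and, named after its values were seen, of the adhesion gene Cadm1 (chromosome 9, 47787971 to 47818817), at 747 and 0 SRPBM in control and 937, 1169 and 1088 in triptolide. The median tested circRNA had 2.6 junction reads per library. In simulations of changes among circRNAs with a mean of at least 20 reads, 6 of 100 4-fold changes were recovered, so a count of 0 does not show that few circRNAs changed.

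**Figure D3:**
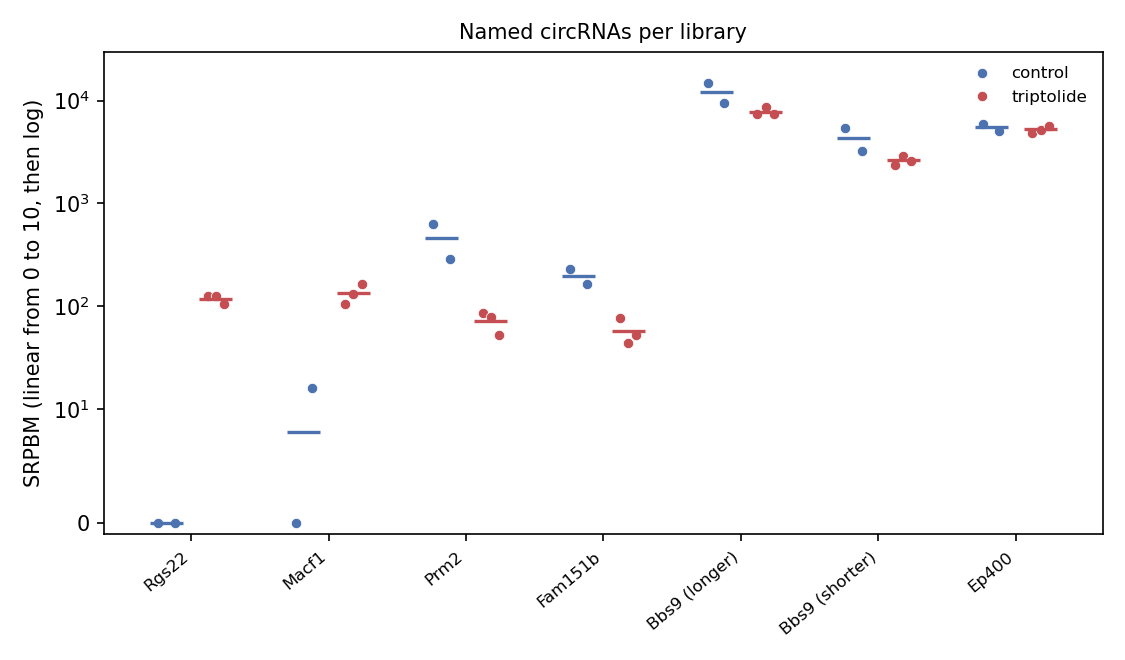
SRPBM per library of 7 named circRNAs, 2 control and 3 triptolide points with a bar at the group mean, on an axis linear from 0 to 10 and logarithmic above. Prm2 has 52 to 86 SRPBM in triptolide against 290 and 624 in control, and Ep400 averages 5232 and 5488.

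By host gene, 202 tested circRNAs came from genes of the fixed lists and 0 passed in limma. The 24 circRNAs of meiotic prophase genes had a median log2 change of -0.33, and those of axoneme genes (61), the piRNA pathway (28), sperm ion channels (25), round spermatid and acrosome genes (18) and blood-testis barrier genes (9) medians of -0.07, -0.20, -0.07, -0.21 and -0.12. The 7 circRNAs of regulators of circRNA formation and the 5 of TFIIH and RNA polymerase II genes, which came from Gtf2h1 and Mnat1, had medians of 0.62 and 0.69. The 7 of listed lncRNA genes had a median of 0.14. Several medians shifted with the control used. Without control 1 they were -0.59 for meiotic prophase, -0.48 for the piRNA pathway, -0.62 for the blood-testis barrier, 0.01 for the axoneme and -0.16 for named lncRNAs. Without control 2 they were -0.02, -0.04, 0.56, 0.19 and 0.49, and 0.08 for sperm ion channels. Triptolide libraries moved some medians too. Without triptolide B they were 0.43 for regulators of circRNA formation and -0.385 for round spermatids and acrosome. Without triptolide A they were -0.11 for the latter and 0.035 for the axoneme. Leaving aside circRNAs listed at 0 in 1 library alone, the median for meiotic prophase was -0.41. None of these 9 lists stood apart (smallest camera adjusted p = 0.34, and 0.81 with an estimated correlation). For the axoneme, blood-testis barrier and named lncRNA lists the median and camera's direction differed in sign. Fry's mixed test, which does not compare a list with the other circRNAs, gave an adjusted p of 0.025 for meiotic prophase. Adjusted over the list alone, 2 of 2 circRNAs of elongating spermatid genes passed, those of Prm2 and of Odf2, an outer dense fibre gene, listed at 0 in both controls and at 19, 70 and 43 SRPBM in triptolide. So did 2 of 3 of spermatid chromatin genes, those of Prm2 and of the histone demethylase gene Kdm3a, at 35 and 41 SRPBM in control and listed at 0 in triptolide. With so few members that adjustment stays close to the unadjusted p, which was 0.036 for Odf2 in limma (adjusted p = 0.68 over all circRNAs). Of all tested circRNAs, 6.6% had an unadjusted p under 0.05. For spermatogonia (1 tested), immune cells (3), p53 targets (1), heat shock (3), glycolysis (3), fatty acid metabolism (2) and drug metabolism (1), 0 passed in limma either way, and the remaining lists had 0 tested circRNAs.

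Total circRNA per library was 354280 ± 6817 SRPBM in control (SD, n = 2) and 335690 ± 46890 in triptolide (SD, n = 3), with a two-sided exact permutation p of 0.6, in a design whose smallest p of 0.1 lets no difference pass 0.05. The number of circRNAs above 0 was 4997 ± 689 and 4911 ± 629 (exact permutation p = 1). The difference in total was -18591 SRPBM, -45600 without triptolide B, -3512 without triptolide C and -31473 leaving aside circRNAs listed at 0 in 1 library alone.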

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

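The alternatives for lncRNA loci, the edgeR runs on mRNA or lncRNA transcripts without TMM, on mRNA with a mean count filter or with robust dispersion, limma on log2(FPKM + 1) and voom, limma on log2(CPM + 0.5), DESeq2 and unfiltered edgeR on circRNA reads, the circRNA list medians with 1 library left out, the runs leaving aside circRNAs at 0 in 1 library alone, and the gene list runs were chosen after seeing the data; the others were fixed before. For mRNA transcripts, the 6 calls became 169, 175 and 252 with limma on log2(FPKM + 1), + 0.5 and + 0.1, 107 with quantile normalization, 199 with median scaling, 219 without trend, 1138 with library weights, 90 at a mean FPKM of at least 5, 8134 with DESeq2 and 0 with voom; the cause was not tested beyond the simulations. It was 0 to 0 with each library left out, where a lone control is assumed to vary like the triptolide libraries. With the replicate number as a block edgeR called 0, and same-numbered libraries deviated together with r of -0.02 and 0.04 across transcripts, which gives no sign of pairing. No paired analysis was possible for lncRNAs and circRNAs because some of their columns carry no number.

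For single lncRNA transcripts, the 0 calls became 2 with limma on log2(CPM + 0.5), 3 with + 1, 2 with quantile normalization, median scaling or library weights, 79 without trend, 39 with no filter and 327 with DESeq2. The 501 locus calls were 376 to 551 under other scalings, filters and tools, with 364 of them called by DESeq2 too; they were 323 at 2-fold or more and 307 without loci that have antisense or intronic transcripts, where fewer pass or are tested by construction, and 269 to 588 with 1 library left out. None of the 501 that were tested again changed sign in any of these. Of 472 values of 36 named loci under alternatives, 30 lost the call and 2 gained it. Of 138 values of 7 named mRNA transcripts, 16 lost and 37 gained it, and of 231 of 15 named circRNAs 12 gained it. For circRNAs, the 0 calls became 36 among those above 0 in at least 1 library (34 higher, 2 lower), 1 (lower) among those above 0 in all 5 libraries, and 0 to 130 with 1 library left out (122 higher and 8 lower without control 2). They became 5 with edgeR on recovered reads and no filter, those of Prm2, Rgs22, Rsph1 and Alms1 and 1 on chromosome 3 with no host named (the last 3 named after their values were seen), and stayed at 0 with DESeq2 and when circRNAs at 0 in 1 library alone were left aside; the cause was not tested. The Ep400 difference changed sign, to 0.018 under median scaling and 0.106 with DESeq2, and lay between -0.185 (without control 2) and 0.051 (without control 1) with 1 library left out. Of the gene lists 0 passed with camera, with an estimated correlation and with fry's directional test. The alternatives of the host gene, neighbour and mRNA list tests were not run because those tests lacked gene names.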

Other observations

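Apart from the tests of loci far from coding genes, thinning, reads shared within a gene or locus, and lncRNA length, the tests in this part were chosen only after the result was seen. A pair of the loci that rose lie close together on chromosome 7, both on the minus strand. XLOC_175191 (125289506 to 125291157) had 0 and 0 against 12, 5 and 30 counts. The antisense locus at 4930533L02Rik (125306594 to 125320287) had 44 and 54 against 274, 290 and 433 counts. Among host genes of circRNAs, Dnah8, an axonemal dynein of sperm, had the most, 51, while the 20 circRNAs of Bbs9 made up 4.52% of the mean SRPBM. Of the 11957 circRNAs, 6500 were above 0 in 1 library.

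Malat1 and most called lncRNA loci were higher in triptolide. Stray reads from coding genes within 10 kb are argued against as the only source of the larger share of rises. Of 210 called loci over 10 kb from any RefSeq coding gene, 128 were rises (61.0%, 95% exact binomial interval 54.0% to 67.6%). Within 10 kb stray reads stay open, since 217 of 291 called loci were rises (74.6%, two-sided Fisher's exact p = 0.0013 against the farther loci). The interval and the p treat loci as independent, although all share the same 5 libraries. Signal reaching past 10 kb was not tested. Scaling stays open, because leaving out TMM hardly moved the median log2 change of all loci (0.0020 to 0.00037). The 68.1% of rises it gave therefore decides nothing. Intronic loci exceeded intergenic ones by a median of 0.043, with an SD of 0.72 among intronic loci. The 95% bootstrap interval of that difference was -0.0067 to 0.136, with loci resampled as independent. No large excess of intronic loci was thus seen. A small one stays open, and with it more unspliced RNA in triptolide. A response to triptolide stays open too and untested, as fragment length separated the groups as well and was not tested against it. The 10 splits of the 5 libraries are too few for a share under 0.05: 1 split, the real one, called 501 loci, and the highest other called 1.

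In the mRNA table, 765 transcripts were at 0 in both controls and above 5 counts in all 3 triptolide libraries, against at most 224 when another pair took the place of the controls, while the reverse held for 227, against at most 443 for another pair, triptolide 1 and 3. Library size is argued against, since 719 were left after thinning to the smallest total, against at most 219. Whether reads moved to another transcript of the same gene cannot be told apart from expression, since 0 transcripts are paired with a gene, and an effect of triptolide stays open and untested. Among lncRNAs, 10 of the 79 tested loci with several transcripts that held such a transcript were called higher (12.7%), with a median locus change of 0.08, which leaves it open too. At XLOC_015689 (chromosome 10), an example picked after its values were seen, transcript TCONS_00026974 had 975 and 1130 CPM in control and 0 in every triptolide library, while the whole locus went from 4328 ± 393 to 2448 ± 204 CPM.

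The tilt of mRNA changes with genomic span was 0.45 between the 10% of transcripts with the longest and the 10% with the shortest spans, and 0.60 among the most abundant 25%. Shorter fragments sample short transcripts better. With the genomic span, introns included, taken as the length, that predicts a median shift of 0.045 for the 3274 transcripts of the shortest 10% over 400 bases. Their observed median was -0.285, the opposite way, which argues against such sampling. Spliced lengths were not used. By locus span, lncRNA loci tilted the other way, by -0.111 (95% bootstrap interval -0.17 to -0.036). That argues against an effect of genomic span on every RNA of these libraries. The interval resampled loci as independent, although all share the same 5 libraries, and the lncRNA tilt was not computed per library. An effect of spliced length was not tested. Library size stays open, since thinning to the smallest total left 0.457, but fold changes are already scaled to library size, so the bound set beforehand was wrong for a test that could hardly move the tilt, and a response to triptolide stays open and untested, since the table names no genes and triptolide 2 lay with the controls. For the 6 calls in this table the 10 splits are again too few: 1 split, the real one, called as many, and the highest other called 0.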
